A study of Mus musculus with 2 samples.

How the data were processed

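Poly(A)+ RNA of interscapular brown adipose tissue from male C57BL/6N mice was sequenced as native RNA on a nanopore, with 1 control and 1 cold library. Per the labels' protocols, RNA was selected on oligo(dT) beads in consecutive rounds, and libraries were made from 500 ng of poly(A)+ RNA with the SQK-RNA002 kit. The kit joins its adapter to poly(A) tails and reads RNA without amplification. Groups were taken from the treatment characteristic in the labels. The protocol field of both samples describes the same 24 h at 4 °C, which the control characteristic contradicts, and the extraction protocol speaks of another fat depot than the tissue field. The design text gives 3 mice for the cold pool and no number for the control. Single housing is stated only with the cold treatment.

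The deposited files hold whole-number read counts per transcript, made by the authors, with an Ensembl transcript identifier for each. They are not normalized, and the lowest count listed is 1, so transcripts at 0 are not listed. The submitters' processing notes name minimap2 as a tool and GRCm38 as the genome build. The aligner version, the annotation release, and how reads that match several transcripts were counted are not given in the sources used here. The control file lists 29924 transcripts with 1698124 reads, and the cold file 27820 transcripts with 1215617 reads.

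Transcripts were matched to genes by identifier without its version in GENCODE mouse release M21, also on GRCm38, from which all coordinates come (counted from 1). No gene was found for 75 transcripts of the control (970 reads, 0.0571%) and 79 of the cold library (793 reads, 0.0652%). These were kept as single entries in the library size and given no gene name. Reads were summed to genes, giving 15622 with at least 1 read. Of these, 14205 were detected in the control and 13721 in the cold library, or 13466 in the control after thinning to 1215617 reads.

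Library sizes were multiplied by edgeR TMM factors (0.940 and 1.06), giving effective sizes of 1595479 and 1293824 reads. The ratio of cold to control was formed from scaled counts, and log2 ratios used a prior of 0.5 reads. Its 95% interval came from the exact Clopper-Pearson interval of the cold share of both counts. A gene at 0 in 1 library was set against a floor of 3 reads and given as a bound, which leaves out the counting error of the other library. Genes at least 2-fold apart were counted among those with at least 20 summed reads and an interval that excluded a ratio of 1. This is a description of 2 libraries. It is not a test of the conditions, and intervals and floors cover counting error only.

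Gene lists were written before the data were examined. There were 29: brown fat thermogenesis and identity, adrenergic and cAMP response, fatty acid synthesis, triglyceride synthesis and lipid droplets, lipolysis, lipid uptake and fatty acid activation, fatty acid oxidation, glucose uptake and glycolysis, tricarboxylic acid cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, creatine and calcium cycling, cholesterol synthesis, ribosomal proteins, protein folding and proteasome, secreted factors of adipose tissue, adipocyte transcription factors and identity, and interferon response, and markers of white adipocytes, skeletal muscle, endothelium, macrophages and monocytes, lymphocytes, mural and smooth muscle, fibroblasts and matrix, nerve and Schwann cells, erythrocytes, proliferation and nuclear RNA. Some genes stand on more than 1 list. Each list was given as the median log2 ratio of members with at least 20 summed reads, with a 95% interval from 1000 Poisson redraws of both libraries. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins.

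Shares of a gene's reads per transcript were compared for genes with at least 100 reads in each library, with exact binomial intervals per library and a Newcombe interval for the difference. Shares of a library's reads have exact binomial intervals.

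Genes named in the text were chosen by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest ratios among genes with at least 100 summed reads. From each list it takes up to 2 members with the highest ratios, 2 with the lowest and 2 with the highest mean level, among those with at least 50 summed reads. It adds Ucp1, Ppargc1a, Dio2, Elovl3, Cidea, Gk, Fgf21, Lpl, Fasn, Adipoq and Lep whatever their values, the 10 most abundant genes of each library and the 8 genes with the largest difference in a transcript's share. The rule gave 154 genes before the 8 of the transcript shares. The text describes part of them and summarises the rest by group. Egr1, Ryr1, Bmp8b, Nr4a1, Alpl, Nnt, mt-Nd6 and the transcripts of Adcy3, Ppargc1a, Ckb and Gmpr were named after their values were seen. Gene families with near-identical copies, such as the globin genes, ribosomal protein genes and their processed copies, Gapdh, the MHC genes and the acyl-CoA thioesterases, can share reads, so their values are uncertain.

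The calculation was tested on simulated Poisson counts for the real genes, with 200 genes changed by known amounts. The simulated cold library was shallower than the real one, so the rates below belong to that lower depth. Of genes simulated at 4-fold, 100% of the higher and 96.0% of the lower ones were called, and of those at 2.5-fold, 90.0% and 80.0%. Of 7065 unchanged genes, 103 were called by counting noise. The intervals held the true ratio in 96.2% of genes.

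Alternatives planned before the data were examined were scaling by total count, by total count without mitochondrially encoded genes and by DESeq2 size factors (1.10 and 0.909), thinning of the control to the depth of the cold library, other minimum counts, a prior of 5 reads, the most abundant transcript of each gene alone, and other minimum counts for transcripts. Scaling without mitochondrially encoded genes and their chromosome 1 copies, and counts without muscle genes, were added after the data were seen. The software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Transcripts outside the deposited annotation, read ends, tail lengths and RNA modifications were not analysed here.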

Results

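Direct RNA sequencing on a nanopore, which reads native poly(A)+ RNA molecules one at a time from the 3' end, was applied to interscapular brown adipose tissue, the heat-producing fat depot between the shoulder blades. The animals were male C57BL/6N mice of 20 weeks. There was 1 control library and 1 cold library. The cold library was a pool of 3 mice kept alone in their cages at 4 °C for 24 h, and general housing was at 22 to 24 °C. The pool size of the control library was not given in the sources used here. The control library held 1698124 reads and the cold library 1215617 reads, over 29924 and 27820 listed transcripts. With 1 library per group there was no spread between replicates, so no test between conditions was possible and no p-values are given. Values in parentheses after a fold or a share are 95% counting intervals, which compare these 2 libraries and not the conditions.

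The comparison asks which transcripts differed in amount between brown fat of control mice and of mice after 24 h in the cold. Genes listed for brown fat thermogenesis and identity and for the uptake of lipid were on balance higher in the cold library. Those for making fatty acids from citrate and acetyl-CoA were lower. Nuclear genes of oxidative phosphorylation were slightly lower, with a median log2 ratio of -0.21, or -0.03 with total counts. Among genes with at least 100 reads over both libraries, Ckb, the cytosolic creatine kinase, had the highest ratio, 27.4-fold (20.6 to 37.3), with 49 reads in the control and 1089 in the cold library. Gmpr, the reductase that turns GMP into IMP, was 21.5-fold higher (18.3 to 25.4), with 159 and 2769 reads. At the other end of these genes, Slc2a5, a fructose transporter, was 25.1-fold lower (9.57 to 93.7) and Acly, which splits citrate to acetyl-CoA in the cytosol, 7.17-fold lower (6.47 to 7.96).

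Of 7529 genes with at least 20 reads over both libraries, 316 were at least 2-fold higher and 307 at least 2-fold lower in the cold library with an interval that excluded a ratio of 1. The higher share of this count was 50.7%. It depended on the scaling, being 73.4% (522 higher, 189 lower) with total counts and 67.4% (450 and 218) with total counts free of mitochondrially encoded genes. With DESeq2 size factors it was 46.9% (300 and 340). The total-count scalings shifted the median log2 ratio of all genes upwards by 0.18 and 0.13, and list medians moved with it. A list median below 0 by less than that shift therefore turned positive. Ratios below are relative to the trimmed-mean scaling, under which the median gene was at a log2 ratio of 0.00.

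Further genes among the 12 highest ratios, again of genes with at least 100 reads, had varied functions. Slc25a34, a mitochondrial carrier, was 15.7-fold higher (8.51 to 32.2), Nnmt, which methylates nicotinamide, 11.4-fold higher (7.91 to 17.0), and Cdkn1a, an inhibitor of cyclin-dependent kinases, 9.78-fold higher (6.58 to 15.1). Atp1b1, a subunit of the sodium pump, was 8.40-fold higher (4.95 to 15.2). Adcy3, an adenylyl cyclase that makes cAMP, was 6.82-fold higher (5.80 to 8.05) and Cntfr, the receptor for ciliary neurotrophic factor, 6.41-fold higher (3.95 to 10.9). The muscle genes Mb and Tnni2 were in this group too, at 6.49-fold (4.28 to 10.2) and 5.97-fold (4.19 to 8.71). On the lower side stood Ntrk3, a neurotrophin receptor, at 10.1-fold lower (5.13 to 22.6), Tmem45b at 5.88-fold lower (4.53 to 7.74), and the long non-coding RNA gene Gm26917 at 5.22-fold lower (3.07 to 9.47). Car3, a carbonic anhydrase abundant in adipocytes, was 4.47-fold lower (4.02 to 4.98), and Aoc3, an amine oxidase of the adipocyte surface, was 4.14-fold lower (3.04 to 5.74). On GRCm38, Ckb lies on chromosome 12 (111669361 to 111672338), Gmpr on chromosome 13 (45507444 to 45553800), Slc2a5 on chromosome 4 (150119283 to 150144169) and Acly on chromosome 11 (100476353 to 100528000).

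**Figure D1:**
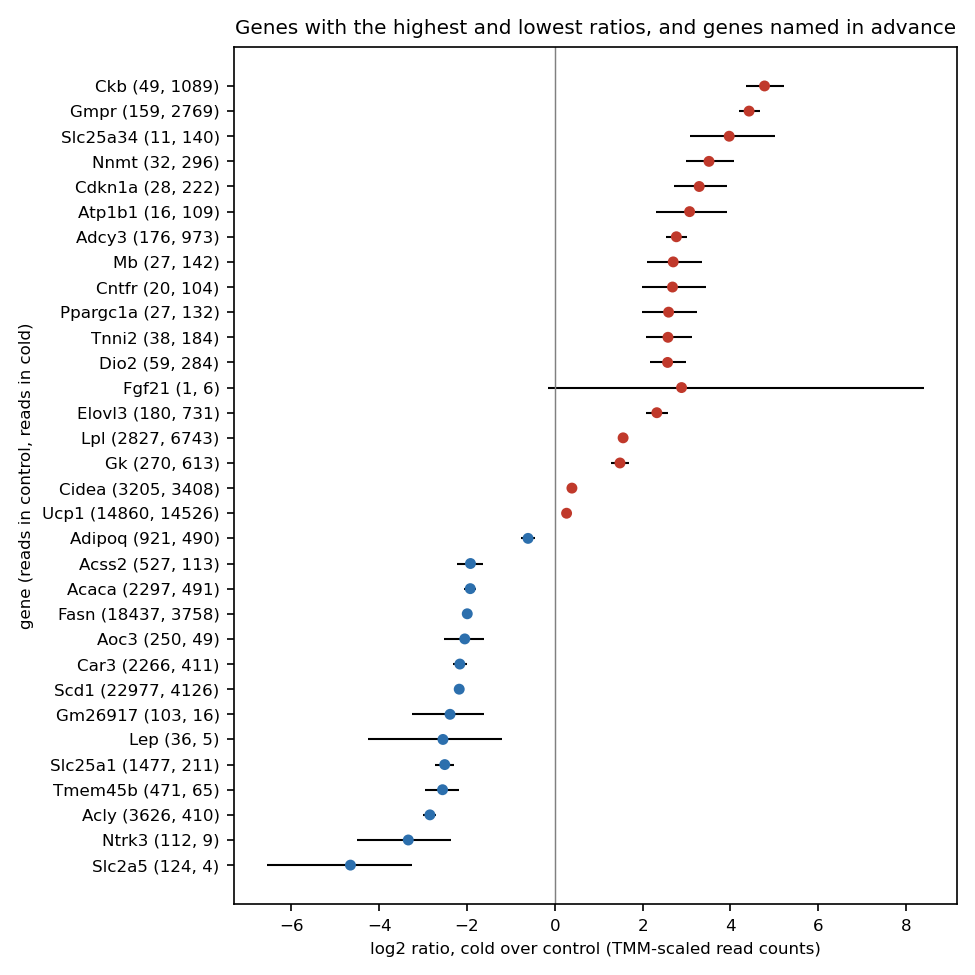
Log2 ratio of cold over control (x axis, scaled read counts with no prior) for the 12 highest and 12 lowest genes with at least 100 reads and for genes named in advance, with 95% counting intervals as bars and the reads in control and cold beside each name. Ckb stands at the top with 49 and 1089 reads and Slc2a5 at the bottom with 124 and 4, while the bar of Fgf21 (1 and 6 reads) crosses 0.

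Genes of brown fat thermogenesis and identity had a median log2 ratio of 0.33 (0.20 to 0.52) over 24 measured members, at percentile 99.8 of 10000 random lists of like expression, and 0.51 with total counts. Their intervals lay above a ratio of 1 for 12 members and below it for 2, Cox8b and Nrg4. Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), was among the smaller differences. It was 1.21-fold higher (1.18 to 1.23) and made up 0.875% of reads (0.861 to 0.889) in the control and 1.19% (1.18 to 1.21) in the cold library. Larger ratios were found for Ppargc1a, a coactivator of mitochondrial genes, at 6.03-fold higher (3.96 to 9.49), and Dio2, which activates thyroid hormone, at 5.94-fold higher (4.47 to 8.0). Elovl3, a fatty acid elongase, was 5.01-fold higher (4.25 to 5.93), Gk, glycerol kinase, 2.80-fold (2.42 to 3.24), and the lipid droplet protein Cidea 1.31-fold (1.25 to 1.38). Cox8b, a cytochrome c oxidase subunit, was 1.39-fold lower (1.32 to 1.46), and the secreted factor Nrg4 1.59-fold lower (1.24 to 2.04). Fgf21 had 1 read in the control and 6 in the cold library, a ratio of 7.40 (0.898 to 340), so a difference was not detectable at this depth.

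Genes of the adrenergic and cAMP response had a median of 0.34 (0.20 to 0.68) over 16 members, at percentile 98.7. It was 0.60 over members with at least 1 summed read, 0.50 over those with at least 100, and 0.52 with total counts. Their intervals lay above a ratio of 1 for 7 members, among them Pde4d, a cAMP phosphodiesterase, at 2.54-fold higher (1.64 to 4.01), and Rgs2, a regulator of G protein signalling, at 2.15-fold (1.46 to 3.21). Cebpb and Pdk4, the most abundant members, were 1.14-fold (1.04 to 1.26) and 1.18-fold higher (1.07 to 1.30). The immediate early gene Egr1, singled out after its values were seen, was the member with an interval below 1, at 12.2-fold lower (3.09 to 105) on 30 and 2 reads.

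Creatine and calcium cycling had a median of 2.07 (1.41 to 2.42) over 8 members, at percentile 100. Besides Ckb, the mitochondrial creatine kinase Ckmt2 was 3.90-fold higher (2.00 to 8.21) and the calcium pump Atp2a1 4.95-fold higher (3.80 to 6.51). The related pump Atp2a2, with 288 and 364 reads, was 1.56-fold higher (1.33 to 1.83), a log2 ratio of 0.64, which was 0.29 from its most abundant transcript alone. Ckmt2, Atp2a1 and Ryr1 are also transcribed in skeletal muscle, whose markers were higher in the cold library as well. Without these 3 genes, a choice made after the values were seen, the median was 0.64, which is the value of Atp2a2. It has no interval or percentile and is not shown to be free of muscle RNA.

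**Figure D2:**
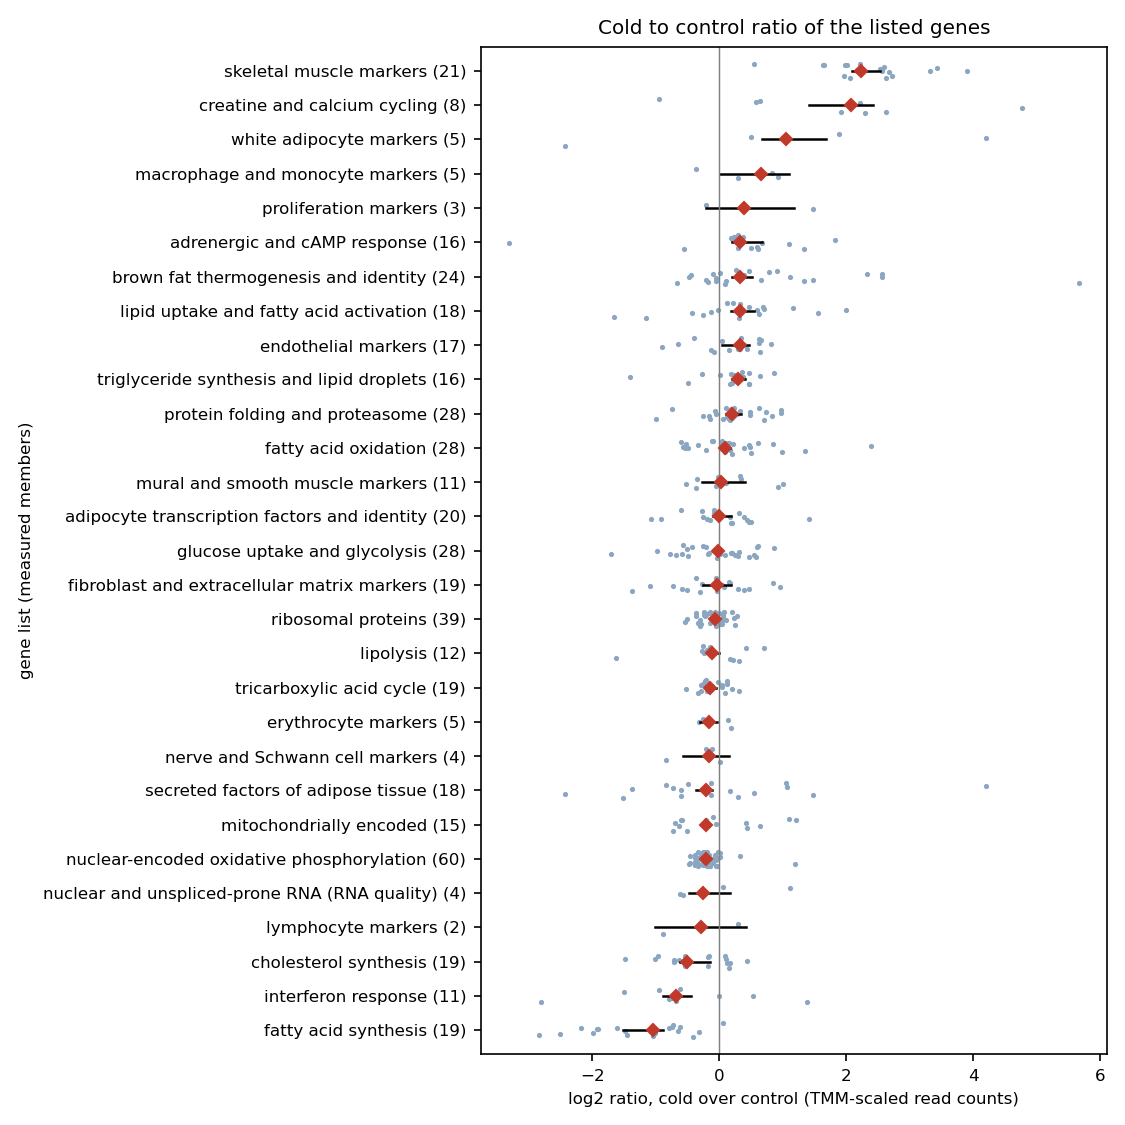
Log2 ratio of cold over control (x axis, scaled read counts) for the measured members (blue points) of each of 29 gene lists (y axis), with the list median as a red diamond and its 95% interval from Poisson redraws as a black bar. Skeletal muscle markers have the highest median, 2.24, and fatty acid synthesis the lowest, -1.04.

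Fatty acid synthesis was the list with the lowest median, -1.04 (-1.51 to -0.88) over 19 members, below all 10000 random lists of like expression (percentile 0.00). In 17 of the 19 the interval lay below a ratio of 1, and 10 were at least 2-fold lower. The list took 3.6% of reads (3.57 to 3.62) in the control and 1.13% (1.11 to 1.15) in the cold library. Most of this was Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547), and Scd1, the desaturase that makes oleate (chromosome 19, 44394455 to 44407879). Fasn was 3.98-fold lower (3.84 to 4.12), with 18437 and 3758 reads, and Scd1 4.52-fold lower (4.37 to 4.67), with 22977 and 4126. The steps before the synthase were lower too. Slc25a1, which carries citrate out of mitochondria, was 5.68-fold lower (4.91 to 6.59). Acaca, which makes malonyl-CoA, was 3.79-fold lower (3.44 to 4.19), and Acss2, which activates acetate, was 3.78-fold lower (3.08 to 4.68). Acacb, the second acetyl-CoA carboxylase, was only 1.24-fold lower (1.12 to 1.38). The elongase Elovl6 was close to equal at 1.04-fold higher (0.941 to 1.15).

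Transcripts for taking up and storing lipid were on balance higher in the cold library. Lipid uptake and fatty acid activation had a median of 0.32 (0.18 to 0.55) over 18 members, at percentile 99.6, and 0.50 with total counts. Its intervals lay above a ratio of 1 for 9 members. Lpl, the lipase that frees fatty acids from circulating triglyceride, was 2.94-fold higher (2.81 to 3.07), with 2827 and 6743 reads. The fatty acid binding protein Fabp3, which muscle also makes, was 3.99-fold higher (3.75 to 4.24), and Fabp4, with 20610 and 20787 reads, 1.24-fold higher (1.22 to 1.27). Fabp5 and Acsl3 were the members with intervals below 1, at 3.18-fold (2.59 to 3.92) and 2.27-fold lower (1.34 to 3.99). Triglyceride synthesis and lipid droplets had a median of 0.30 (0.20 to 0.40) over 16 members, at percentile 99.6, and 0.48 with total counts, with 11 intervals above a ratio of 1 and 3 below. Gpam, the first acyltransferase of glycerolipid synthesis, was 1.82-fold higher (1.59 to 2.08) and Dgat1, which adds the last acyl chain, 1.56-fold (1.37 to 1.79). Agpat2 was 1.4-fold lower (1.34 to 1.47) and the lipid droplet protein Bscl2 1.2-fold lower (1.03 to 1.41).

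Fuel breakdown showed mixed differences. Fatty acid oxidation had a median of 0.09 (0.04 to 0.16) over 28 members, at percentile 96.0, with 11 intervals above a ratio of 1 and 6 below. This median was 0.27 with total counts and 0.23 with total counts free of mitochondrially encoded genes. Cpt1a, which starts the entry of fatty acids into mitochondria, was 5.41-fold higher (2.92 to 10.8) on 13 and 57 reads. The acyl-CoA thioesterase Acot2 was 2.58-fold higher (1.69 to 4.00), while the thiolase Acaa1a was 1.51-fold lower (1.19 to 1.94). Lipolysis had a median of -0.12 (-0.18 to -0.01) over 12 members, at percentile 35.4, which turned to 0.06 with total counts and 0.01 with total counts free of mitochondrially encoded genes. Its intervals lay above a ratio of 1 for 3 members and below it for 5. The lipases Pnpla2 and Lipe were 1.14-fold (1.08 to 1.2) and 1.21-fold lower (1.11 to 1.32), with Pnpla2 at a log2 ratio of -0.19, or -0.08 from its most abundant transcript alone. The list also held Ces1f at 3.18-fold lower (1.66 to 6.58) and Mgll, which splits monoglycerides, at 1.62-fold higher (1.48 to 1.78). Glucose uptake and glycolysis had a median of -0.01 (-0.09 to 0.01) over 28 members, at percentile 74.3, with 11 intervals above a ratio of 1 and 13 below, and turned to 0.17 with total counts and 0.12 with total counts free of mitochondrially encoded genes. Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 3.31-fold lower (2.08 to 5.48), and Pdhb, a subunit of that dehydrogenase, 1.96-fold lower (1.82 to 2.13). The hexokinase Hk1 was 1.83-fold higher (1.19 to 2.86). For Gapdh the ratio was 1.03-fold lower (0.992 to 1.06), a log2 ratio of -0.04, which turned to 0.14 with total counts and to 0.04 from its most abundant transcript alone. The tricarboxylic acid cycle had a median of -0.15 (-0.19 to -0.04) over 19 members, at percentile 37.1, which turned to 0.03 with total counts and was -0.01 with total counts free of mitochondrially encoded genes. Its intervals were above 1 for 3 members and below it for 9, such as Idh2 at 1.43-fold lower (1.17 to 1.76), whereas Idh3a was 1.25-fold higher (1.18 to 1.32).

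Mitochondrially encoded transcripts made up 31.7% of reads (31.6 to 31.8) in the control and 29.4% (29.3 to 29.5) in the cold library. Within them, the rRNAs were higher and most mRNAs lower in the cold library. The share of mitochondrial rRNA was 1.88% (1.86 to 1.90) and 4.83% (4.79 to 4.87), and that of mitochondrial mRNA 29.8% (29.7 to 29.8) and 24.5% (24.4 to 24.6). mt-Rnr1 was 2.13-fold (2.08 to 2.19) and mt-Rnr2 2.32-fold higher (2.28 to 2.35). Of the 13 mRNAs, 10 were below a log2 ratio of 0, and 8 were with total counts, where mt-Nd2 and mt-Nd6 lay above 0. mt-Co2 was 1.66-fold lower (1.64 to 1.68), mt-Atp6 1.61-fold lower (1.59 to 1.63) and mt-Cytb 1.51-fold lower (1.49 to 1.52). The list of 15 genes had a median of -0.21 (-0.24 to -0.18), at percentile 12.9, and -0.03 with total counts and -0.08 with total counts free of mitochondrially encoded genes. The 60 measured nuclear genes of oxidative phosphorylation had a median of -0.21 (-0.24 to -0.18), at percentile 0.74, and likewise -0.03 and -0.08 with these scalings. Their intervals lay below a ratio of 1 for 47 members, such as Ndufa13 at 1.39-fold (1.26 to 1.54) and Ndufb8 at 1.38-fold lower (1.29 to 1.48). They lay above it for Cycs, cytochrome c, at 1.26-fold (1.2 to 1.32), and Atp5g1 at 2.31-fold (1.48 to 3.67), a log2 ratio of 1.2, which was 0.48 from its most abundant transcript alone.

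In each library the 10 most abundant genes were mitochondrially encoded or pseudogenes that copy mitochondrial genes on chromosome 1. These 10 took 34.7% of reads (34.6 to 34.8) in the control and 28.2% (28.1 to 28.2) in the cold library. The control's were mt-Atp6, mt-Cytb, mt-Nd1, mt-Co2, mt-Nd4, mt-Nd2, mt-Co3, Gm10925, Gm28661 and Gm28437, and mt-Rnr2 took the place of Gm28437 in the cold library. The 7 copies lie between 24611535 and 24616197 on chromosome 1, share 97.2 to 100% of their 31-base words with a mitochondrial gene, and took 9.91% (9.87 to 9.96) and 7.18% of reads (7.14 to 7.23). Reads of a copy and of its mitochondrial gene are therefore uncertain in their split. Merging each pair moved no mRNA's log2 ratio by more than 0.039.

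**Figure D3:**
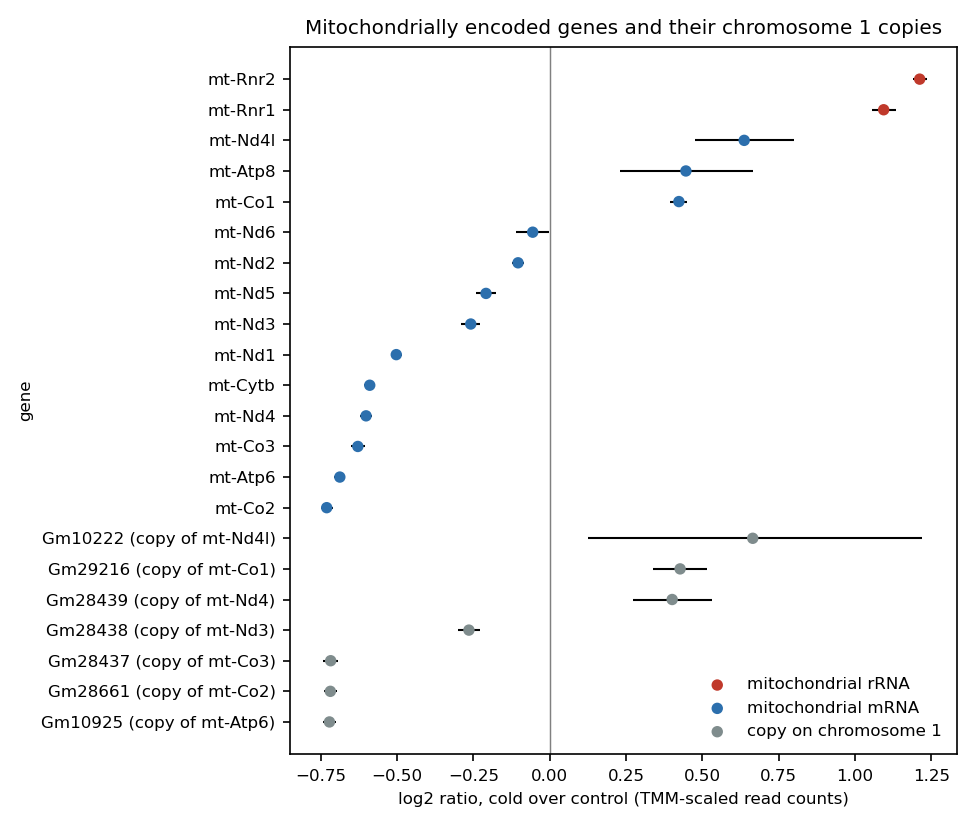
Log2 ratio of cold over control (x axis, scaled read counts) for mitochondrial rRNAs (red), mitochondrial mRNAs (blue) and the chromosome 1 copies (grey), with 95% counting intervals as bars. The rRNAs lie above 1 and 10 of the 13 mRNAs below 0 (8 with total counts, where mt-Nd2 and mt-Nd6 lie above 0).

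Markers of other cell types were compared in the same way. Skeletal muscle markers had the highest median of the 29 lists, 2.24 (2.10 to 2.54) over 21 members, at percentile 100, and each of the 21 intervals lay above a ratio of 1. Their share of reads was 0.0460% (0.0428 to 0.0493) in the control and 0.213% (0.205 to 0.222) in the cold library. The skeletal actin Acta1 was 4.68-fold (3.89 to 5.66), the muscle creatine kinase Ckm 4.75-fold (3.61 to 6.32), the enolase Eno3 6.27-fold (3.34 to 12.8) and the myosin light chain Mylpf 3.13-fold higher (2.12 to 4.72). Myl1, another myosin light chain, was 1.46-fold higher (1.17 to 1.82). From the most abundant transcript alone, the log2 ratio of Eno3 was 3.97 in place of 2.60 and that of Myl1 0.18 in place of 0.54. Leaving out muscle genes, a choice made after the values were seen, gave 272 genes at least 2-fold higher in place of 316, and 307 lower.

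Endothelial markers had a median of 0.32 (0.05 to 0.48) over 17 members, at percentile 97.7, and 0.50 with total counts. Its intervals lay above a ratio of 1 for 3 members and below it for 1. Gpihbp1, which anchors Lpl on capillaries, was 1.55-fold (1.23 to 1.97) and Eng 1.56-fold higher (1.25 to 1.96), while the water channel Aqp1 was 1.87-fold lower (1.45 to 2.43). White adipocyte markers had a median of 1.05 (0.68 to 1.68) at percentile 99.9, over only 5 members, with 3 intervals above a ratio of 1 and 1 below. Npr3, a natriuretic peptide receptor, was 3.73-fold (2.91 to 4.81) and Retn, resistin, 2.08-fold higher (1.53 to 2.84), and Lep, leptin, 5.84-fold lower (2.28 to 19.1) on 36 and 5 reads. Macrophage and monocyte markers had a median of 0.67 (0.01 to 1.10) over 5 members, at percentile 98.2, with Lyz2 1.79-fold (1.11 to 2.93) and C1qa 1.91-fold higher (1.06 to 3.54). The intervals of the medians crossed 0 for mural and smooth muscle markers (0.03, -0.27 to 0.40, 11 members, percentile 52.8), fibroblast and extracellular matrix markers (-0.04, -0.26 to 0.19, 19 members, percentile 43.1) and nerve and Schwann cell markers (-0.16, -0.56 to 0.16, 4 members, percentile 26.2). They did so too for lymphocyte markers (-0.29, -1.01 to 0.43, 2 members, percentile 23.4) and proliferation markers (0.39, -0.21 to 1.18, 3 members, percentile 84.1). The lymphocyte median was 0.30 with at least 1 summed read and -0.88 with at least 100. Within the matrix genes, the basement membrane collagens Col4a1 and Col4a2 were 1.95-fold (1.66 to 2.30) and 1.81-fold higher (1.54 to 2.13), and Col6a2 and Col6a1 were 2.66-fold (1.44 to 5.25) and 2.18-fold lower (1.2 to 4.14). Erythrocyte markers had a median of -0.16 (-0.30 to -0.04) over 5 members, at percentile 30.3, which turned to 0.02 with total counts, as did Hbb-bs from -0.16 to 0.02.

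Interferon response genes had a median of -0.68 (-0.88 to -0.45) over 11 members, at percentile 0.04. With this scaling 9 of the 11 members lay below 0, and the intervals lay below a ratio of 1 for 6 members and above it for 2. B2m, the light chain of MHC class I, was 1.73-fold (1.51 to 1.99) and Bst2 2.91-fold lower (1.51 to 6.05). The 2 members above 0 were Ifi27l2a at 2.62-fold (2.19 to 3.15) and Ifi27 at 1.45-fold higher (1.36 to 1.54). Cholesterol synthesis had a median of -0.50 (-0.62 to -0.14) over 19 members, at percentile 0.04, and -0.32 with total counts. Its intervals were below 1 for 6 members and held 1 for the other 13. The 6 included Insig1, which retains sterol-regulated factors in the endoplasmic reticulum, at 2.81-fold (2.25 to 3.55), and the squalene synthase Fdft1 at 2.05-fold lower (1.15 to 3.84). Hmgcs1 was close to equal at 1.11-fold higher (0.913 to 1.35). Protein folding and proteasome genes had a median of 0.20 (0.11 to 0.35) over 28 members, at percentile 97.3, and 0.38 with total counts and 0.33 with total counts free of mitochondrially encoded genes. Its intervals lay above a ratio of 1 for 9 members and below it for 1. The chaperones Hsp90aa1, Hspa8 and Hsp90ab1 were 1.96-fold (1.58 to 2.45), 1.63-fold (1.47 to 1.80) and 1.4-fold higher (1.25 to 1.56), and Xbp1, a factor of the unfolded protein response, was 1.69-fold lower (1.13 to 2.55). Ribosomal proteins had a median of -0.07 (-0.13 to -0.02) over 39 members, at percentile 45.3, which turned to 0.11 with total counts and 0.06 with total counts free of mitochondrially encoded genes.

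Secreted factors of adipose tissue had a median of -0.20 (-0.37 to -0.11) over 18 members, at percentile 8.58, with 6 intervals above a ratio of 1 and 8 below. It was -0.02 with total counts, -0.07 with total counts free of mitochondrially encoded genes and -0.38 over members with at least 100 summed reads. Adipoq, adiponectin, was 1.52-fold lower (1.36 to 1.70), the retinol carrier Rbp4 2.88-fold lower (2.15 to 3.90), and the chemokine Cxcl14 2.12-fold higher (1.35 to 3.39). Adipocyte transcription factors and identity genes had a median of 0.00 (-0.10 to 0.18) and a mean of 0.02 over 20 members, at percentile 62.6, with 8 intervals above a ratio of 1 and 3 below. Klf15 was 2.68-fold higher (1.82 to 4.00) and the clock output factor Dbp 2.12-fold lower (1.62 to 2.79). The nuclear RNAs used as a sign of RNA quality had a median of -0.26 (-0.47 to 0.17) over 4 members, at percentile 15.1, and 0.06 with a minimum of 1 or of 100 summed reads, with Neat1 at 1.04-fold higher (0.887 to 1.23) and Gas5 at 1.54-fold lower (0.974 to 2.48).

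The use of transcripts within a gene was compared for 980 genes with at least 100 reads in each library and at least 2 listed transcripts. In 50 of them the share of a transcript differed by at least 10 percentage points with an interval that excluded 0, and in 7 by at least 20 points. Each transcript of a gene was compared, and how many such genes counting error alone would give was not estimated. With a minimum of 50 reads in each library the count of 50 became 138, and 3 of the 8 largest differences were shared. At the minimum of 100 the largest difference was in Tspan18, a tetraspanin gene on chromosome 2. Its short 3-exon transcript Tspan18-205 (93311263 to 93312515) took 10.3% of the gene's reads (6.12 to 16.0) in the control and 64.3% (56.5 to 71.5) in the cold library. The 10-exon coding transcript Tspan18-202 had the opposite order, with 55.8% (47.8 to 63.5) and 21.4% (15.5 to 28.4). In Tpm1, a tropomyosin gene of muscle and other cells, Tpm1-205 took 22.4% (15.6 to 30.4) and 60.8% (52.5 to 68.7). This stood beside the higher muscle markers of the cold library. In 1700037H04Rik a transcript annotated with a retained intron, 1700037H04Rik-204, took 34.1% (31 to 37.2) and 65.5% (62.2 to 68.6).

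Among the other genes with large differences, Tmem259-201 took 53.7% (46.6 to 60.6) and 77.2% (70.8 to 82.7) of its gene's reads. Tef is a transcription factor of the clock output family with more than 1 start site. Its transcript Tef-202 took 92.2% (86.8 to 95.9) in the control and 70.8% (61.5 to 79.0) in the cold library, and Tef-201 took 7.14% (3.62 to 12.4) and 26.5% (18.7 to 35.7). Tecr encodes the last enzyme of the fatty acid elongation cycle, and Tecr-201 took 42.9% (38.8 to 47.0) and 63.3% (56.3 to 69.9). Polr1d-201, from a subunit gene of RNA polymerases, took 34.0% (29.0 to 39.3) and 54.1% (47.6 to 60.5). Ctsl-201, from the gene of the lysosomal protease cathepsin L, took 60.0% (49.7 to 69.7) and 40.5% (31.3 to 50.3). Reads begin at the 3' end and can stop short, so transcripts that differ only at the 5' end are uncertain.

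**Figure D4:**
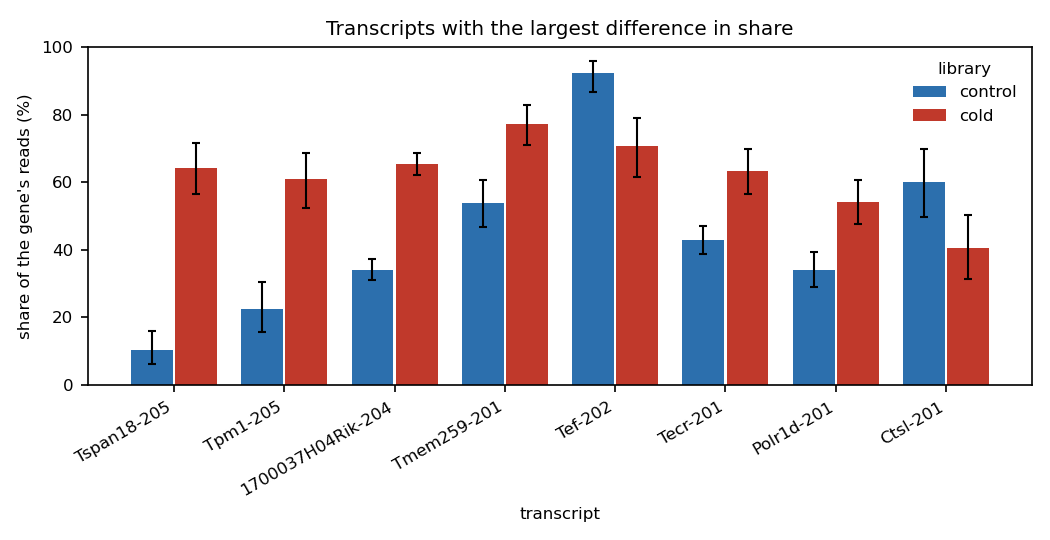
Share of the gene's reads (y axis, percent) given to the transcript with the largest difference in each of 8 genes, in the control (blue) and cold (red) library, with exact 95% binomial intervals as bars. Tspan18-205 goes from 10.3% to 64.3%, and Tef-202 and Ctsl-201 are lower in the cold library.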

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

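The alternatives without mitochondrially encoded genes and their chromosome 1 copies, and without muscle genes, were chosen after the data were seen, and the rest were planned. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The thinned control gave 314 genes higher and 254 lower, and DESeq2 size factors 300 and 340. Under both, each list median whose interval lay off 0 kept its sign. Under any scaling the medians of skeletal muscle, creatine and calcium cycling, thermogenesis, lipid uptake, triglyceride synthesis, fatty acid synthesis, cholesterol synthesis and interferon response kept their sign. Depth limits genes with few reads. The pseudocount settings for normalized values were not run, since the files hold counts, and the prior does not enter the 2-fold counts.

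Total counts gave 522 genes higher and 189 lower, and a minimum of 100 summed reads gave 93 and 63, where fewer genes were tested. Total counts turned the medians of lipolysis to 0.061, the tricarboxylic acid cycle to 0.034, ribosomal proteins to 0.11 and erythrocyte markers to 0.021, with Hbb-bs at 0.021 and mt-Nd2 at 0.076. They moved the medians of fatty acid synthesis to -0.86, triglyceride synthesis to 0.48, fatty acid oxidation to 0.27, glycolysis to 0.17, nuclear oxidative phosphorylation to -0.029, mitochondrially encoded genes to -0.029, protein folding to 0.38, secreted factors to -0.021 and endothelial markers to 0.50. Without mitochondrially encoded genes in the total, lipolysis turned to 0.014, ribosomal proteins to 0.061 and mt-Nd2 to 0.029. The medians of triglyceride synthesis (0.43), fatty acid oxidation (0.23), glycolysis (0.12), the tricarboxylic acid cycle (-0.013), nuclear oxidative phosphorylation (-0.077), mitochondrially encoded genes (-0.076), secreted factors (-0.068) and erythrocyte markers (-0.026) moved. Without the chromosome 1 copies too, glycolysis was at 0.047, nuclear oxidative phosphorylation at -0.15, mitochondrially encoded genes at -0.15 and ribosomal proteins at -0.01. A scaling adds the same shift to each gene, so these moves follow from its construction.

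Of the 154 named genes, total counts moved 59 upwards beyond their counting intervals, of which 5 changed sign. Without mitochondrially encoded genes in the total 42 moved upwards (3 changed sign), without the copies too 19 (2 changed sign), and DESeq2 size factors moved 11 downwards. The most abundant transcript alone was tried for named genes with more than 1 transcript. It moved 7 (Atp2a2 to 0.29, Atp5g1 to 0.48, Eno3 to 3.97, Gapdh to 0.038, Hadhb to 0.18, Myl1 to 0.18 and Pnpla2 to -0.079) and left 101 within their intervals.

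Without Ckmt2, Atp2a1 and Ryr1 the creatine and calcium cycling median was 0.64, the value of Atp2a2. The skeletal muscle median was 2.07 with a prior of 5 reads and 2.06 with at least 100 summed reads, and secreted factors were at -0.38 with that minimum. Without mitochondrially encoded genes the 10 most abundant genes took 22.6% of control and 17.1% of cold reads, and Ucp1 1.28% and 1.69%. The chromosome 1 copies were kept here, and Gm10925, Gm28661 and Gm28437 were among these 10 in both libraries. These shares therefore still hold reads that may be mitochondrial. With at least 50 reads in each library, 138 genes had a transcript share at least 10 points apart in place of 50, and 3 of the 8 largest differences were shared, since genes with fewer reads enter.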

Other observations

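The tests of scaling, of muscle gene expression by adipocytes, of shared mitochondrial reads, of length and GC trends and of adipocyte share were chosen after their results were seen, and the values of single genes in the next paragraph were picked in the same way.

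In the deposited counts, the higher Adcy3 reads of the cold library were spread over several annotated transcripts. Adcy3-201, Adcy3-202, Adcy3-204, Adcy3-207 and Adcy3-208 all end at 4213524 or 4213525. Reads that begin there and stop short may not tell them apart, so their shares are uncertain beyond counting error. Adcy3-201 took 24.4% (18.3 to 31.5) of the gene's reads in the control and 26.4% (23.7 to 29.3) in the cold library, and Adcy3-204 took 23.9% (17.8 to 30.9) and 28.4% (25.6 to 31.3). Gmpr-201 took 100% of 159 and 99.4% of 2769 reads, so the large ratio of Gmpr rests on reads assigned to 1 coding transcript of 9 exons. The retained-intron transcript Ckb-204 took 4.08% (0.498 to 14.0) and 8.72% (7.12 to 10.6) of the Ckb reads, and the difference of 4.64 points has an interval from -5.11 to 8.12. Ppargc1a-203 held all 27 control reads and 120 of 132 cold reads of its gene. It is the only listed transcript of the gene with its 3' end at 51454250. Reads that begin there and stop short can fall to it, so its share does not tell which start site was used. Bmp8b, a secreted factor of brown fat, had 0 and 20 reads, and with the 20 cold reads taken as exact it was at least 8.22-fold higher against a floor of 3 reads in the control library. The exact interval, which covers the counting error of both libraries, reaches lower and starts at 6.09-fold. The thermogenesis median is 0.33 with Bmp8b at 8.22-fold too. The nuclear receptor Nr4a1 was 3.70-fold higher (1.52 to 10.3) and the phosphatase Alpl 4.75-fold higher (2.87 to 8.20). Nnt, a mitochondrial transhydrogenase, had 8 and 11 reads.

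For the higher skeletal muscle transcripts of the cold library, the scaling is argued against as the whole cause. The scalings tried shifted all genes alike, from -0.027 with DESeq2 size factors to 0.18 with total counts. The lowest list median over them, 2.21, follows from these shifts, which are far smaller than the median of 2.24. More muscle RNA in the cold pool is a candidate explanation. Of 29 further muscle genes, written down as outside the sarcomere before their values were seen, 13 had at least 20 reads. That label is loose for Csrp3, Ankrd2 and Trim63. All 13 were above 0, with a median of 1.71 (1.48 to 2.53). Trim63 (1 and 27 reads), Ankrd2 (2 and 32) and Smpx (2 and 18) reached 20 reads only through the cold library. So did Cox6a2 (3 and 46), Csrp3 (6 and 39) and Eef1a2 (7 and 30). This favours ratios above 0, so the count above 0 and the median were partly set by the minimum. Fbp2, Srl and Pygm, with at least 20 reads in the control alone, had log2 ratios of 1.12, 1.71 and 1.25. The rise was uneven: 4 slow fibre markers, with 3 to 4 control reads, had a median of 3.38 and the 17 other listed markers 2.17. Acta1, the listed marker with most cold reads, had 145 and 550. Expression of muscle genes by brown adipocytes cannot be told apart from more muscle RNA, because the reads carry no record of their cell. The list median of 2.24 goes with both. No marker stands on another list, though brown adipocytes are known to make Mb. A response of the tissue to cold stays open and untested, with 1 pool per group.

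Mitochondrial rRNAs were higher and most mitochondrial mRNAs lower in the cold library. Reads shared with the chromosome 1 copies are argued against, as merging moved no mRNA by over 0.039. The scaling is argued against only for the gap between rRNAs and mRNAs. The ratio of rRNA to mRNA reads, which needs no scaling, went from 0.0631 to 0.197, a log2 change of 1.64. How many mRNAs were lower did depend on the scaling, with 10 of 13 below 0 in the main one and 8 with total counts. That test of the copies replaced a first one on the median of the merged mRNAs (-0.26), which decided nothing. For less complete poly(A) selection, nuclear RNAs without a tail had a log2 ratio of -0.12 (-0.31 to 0.07), below the bound of 0.5 set beforehand against it, but histone genes, which can also make polyadenylated mRNA, gave 94.8% of their control reads, so that bound was judged wrong after the result was seen. Other rows differ in direction. Mitochondrial tRNA was at 0.0283% (0.0259 to 0.0310) of control and 0.0682% (0.0636 to 0.0730) of cold reads, and mt-Nd6 at a log2 ratio of -0.06. The non-coding Gm26917 was 5.22-fold lower, but whether it has a poly(A) tail was not examined, so what it says about selection is unclear. Poly(A) selection and a cold response of mitochondrial RNA therefore cannot be told apart and may both contribute.

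Fatty acid synthesis transcripts were lower in the cold library. A trend with transcript length reached at most 0.072 and one with GC content at most 0.025 (log2) over the list's 19 genes, far from the median of -1.04. First versions of these tests, set before the result was seen, used the list median after the trend was removed (-1.08 and -1.03) and were then replaced, as the spread of the length value passed its bound and removing the GC trend moved 0 genes by over 0.1. Fewer adipocytes in the cold pool would lower adipocyte transcripts alike. The 20 adipocyte transcription factor and identity genes, a list fixed beforehand, had a median of -0.001 (-0.171 to 0.255 by bootstrap over members). That list also holds clock genes such as Dbp and Tef, which are not particular to adipocytes. Adipoq (-0.61), Rbp4 (-1.52), Aoc3 (-2.04), Car3 (-2.16) and Lep (-2.43) were lower, while Fabp4 (0.315) and Cidec (0.47) were higher. The median therefore cannot tell whether the cold pool held fewer adipocytes. This test replaced one on 11 adipocyte transcripts picked after their values were seen (median 0.17). A lower need or signal for fatty acid synthesis in the cold is a hypothesis that may explain it and was not tested, as single housing and the pool go with the treatment.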
